A study of Arabidopsis thaliana with 28 samples.

How the data were processed

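Gene expression was measured on 28 Agilent Arabidopsis arrays with 1 colour (Cy3), each hybridised with labelled RNA from shoot apices, leaf primordia included, of 6-day-old seedlings. Per the labels, all plants carried a transgene that fuses a protein to the glucocorticoid receptor (GR) domain behind the strong 35S promoter. In 35S::WOX1:GR the protein is WOX1, a homeobox transcription factor, and in 35S::GFP:GR it is green fluorescent protein. The GR domain keeps a fusion protein out of the nucleus until the steroid dexamethasone (DEX) is added. Cycloheximide (CHX) blocks protein synthesis, and IAA is the plant hormone auxin. DEX was used at 10 µM for 6 hours, CHX at 10 µM for 6 hours and IAA at 20 µM for 3 hours, per the labels.

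Samples were grouped by their titles into 10 groups. WOX1:GR apices treated with mock medium, DEX, CHX or DEX with CHX made 4 groups of 4 arrays, and replicates 1 to 4 were line 1 experiment 1, line 1 experiment 2, line 2 experiment 1 and line 2 experiment 2. GFP:GR mock and GFP:GR DEX had 2 arrays each, 1 per line. A further 4 groups of 2 arrays, again 1 per line, received, per the labels, mock medium or DEX for 6 hours and then mock medium or IAA for 3 hours. Whether DEX stayed in the medium during the last 3 hours, and so whether the treatments overlapped, is not given in the sources used here. Replicates are therefore independent transgenic lines and separate samplings of the same line. Within each group, arrays correlated at 0.973 to 0.995 across genes, and no pair of arrays held identical values.

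Per the file headers, the authors scanned the arrays and quantified spots with Agilent Feature Extraction 10.7.3.1, and the processed intensity of each spot is the brightness on a linear scale after background subtraction with spatial and multiplicative detrending, not normalized between arrays. Mean spot intensity and median local background intensity are given in the same deposited scanner files. The authors' deposited table of the whole series holds linear signal values. Each of its columns equalled the processed intensity of that array divided by 1 constant, to within 0.0210%, and had a median of 1. Genes were not centred in it and its direction is that of the intensity. The software that made it is not given in the sources used here.

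Control spots were left out, which left 43803 spots of 43603 probes. A probe with a non-uniform spot on any array was dropped, which removed 290 probes, and 0 spots were saturated on any of the 28 arrays. Repeated spots of a probe were averaged, without those that Feature Extraction marked as far from the other repeats. Spots well above background made up 67.6% to 76.4% of an array, and the 75th percentile of processed intensity ranged from 1303 to 2785. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.147 with 4 arrays per group and 0.209 with 2. Probes were paired with genes through accessions, locus codes and symbols in a reference table of the TAIR10 assembly. 1 gene was found for 35832 probes, several for 475 and none for 7296. Probe coordinates are those of the array annotation on the TAIR10 build, per the file headers.

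From the deposited intensities, log2 of the processed intensity minus the array's 75th percentile was computed, and all log2 levels below are on that scale. A gene entered if a probe was well above background on every array of at least 1 group. A gene with several probes took the probe with the highest mean over all arrays. This gave 21310 genes from 29752 probes. A linear model with 1 mean per group was fitted over all 28 arrays with limma 3.58.1 (lmFit and eBayes, 18 residual degrees of freedom and a prior of 1.94) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method within each of 12 comparisons, and a gene was called at an adjusted p under 0.05. Errors of fold changes are standard errors (SE) of this fit, and errors of levels are standard deviations (SD). Where a gene was not well above background on any array of a group, its change is given as "at least N-fold". That bound sets the mean of the brighter group against the mean of the dim group, with each dim array at the higher of the probe's own value and the lowest value of any probe well above background on it. No fold is given where both groups were below background. A bounded list median sets genes with 1 dim group at their bound and leaves out genes below background in both groups. It therefore rests on fewer genes where such genes occur, and can exceed the plain median in size.

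The fit was tested on simulated data for the same 28 arrays, in which each of the 21310 genes had its measured overall mean and its measured spread within groups, with random normal errors. For each comparison, 100 genes were then changed 2-fold and 100 others 4-fold, and the listed SAUR genes were lowered 2-fold. Of 100 genes changed 4-fold, 95 were recovered for DEX in WOX1:GR, 90 for DEX with CHX, 87 for CHX, 82 for IAA, 84 for DEX in GFP:GR and 62 for the DEX by IAA difference. Of 100 genes changed 2-fold, 73, 66, 71, 55, 58 and 27 were recovered in the same order. Between 5 and 16 of 21083 unchanged genes were called. The lowered SAUR list was called in each of the 12 comparisons. The simulated errors are independent between genes, so the simulation does not measure false list calls, and it holds neither slide nor line effects. On the measured arrays, splits with 0 genes called gave up to 11 called lists for DEX and 16 for CHX.

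The genes named follow a rule: WOX1; the 10 largest rises and 10 largest falls for DEX in WOX1:GR, DEX with CHX, CHX and IAA; the 3 largest of each for other comparisons; up to 10 genes called alike in 3 DEX comparisons; and up to 4 members, by p, of each list with a called gene. The largest rises and falls needed an adjusted p under 0.05 and a symbol, which 9269 of the tested genes had, and, for comparisons of 2 groups, no overlap between the arrays of the groups. Genes alike in 3 DEX comparisons needed a call in each but no symbol and no lack of overlap, so some carry only a locus code. List members were chosen by p alone. Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and also with an estimated correlation and with fry. Of 530 list members, 524 were found on the array under their locus. The 36 lists were Aux/IAA repressors, auxin-conjugating GH3 enzymes, SAUR small auxin-up RNAs, auxin-induced LBD factors, auxin synthesis, auxin transport, auxin receptors with ARFs, adaxial leaf polarity, abaxial leaf polarity, leaf margin and blade growth, class II TCP factors, shoot meristem and boundary, other WOX genes, type-A response regulators, cytokinin metabolism, mitotic cell cycle, DNA replication, gibberellin, brassinosteroid, ethylene, jasmonate, salicylate and immune response, abscisic acid, heat shock, flavonoids, glucosinolates, cell wall loosening, ribosome and nucleolus, photosynthesis, circadian clock, and 6 lists of markers (root, seed storage, trichome, stomatal lineage, vascular tissue, flowering shoot). Sample groups, comparisons, the named-gene rule, the lists and the alternative settings, apart from those named below as added, were fixed before the data were examined.

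The alternatives were normexp background correction (offset 50), quantile normalization, other filters on dim probes, the mean of a gene's probes, an intensity trend in eBayes, the deposited table, only the groups compared, the replicate (line and experiment within each set) as a block, the slide as a block, and leaving out each array. Fits on 1 experiment or 1 line were added after seeing the data. Replicate numbers pair samples only within a set of groups. In the 4-array WOX1:GR groups the same number is the same line and experiment, where experiment is the replicate number in the sample title. The titles alone do not say that this number marks the same sampling with and without CHX. In the GFP:GR groups and in the IAA experiment the same number is the same line. GFP:GR lines are other lines than WOX1:GR lines, and the blocks of the 3 sets were kept apart. Deviations from group means correlated at 0.586 to 0.654 for the 4 pairs of mock and DEX and at 0.610 to 0.679 for the 4 pairs of CHX and DEX with CHX. For the 4 pairs of CHX and mock, which share no slide, the correlations were -0.0218 to 0.0923. Mock and DEX arrays that were not paired correlated at -0.205 on average and at most at 0.615. The unpaired CHX and DEX with CHX arrays gave -0.216 and 0.299. Pairs within the mock and DEX set, and within the CHX set, also shared a slide, so their correlations do not tell line and experiment from slide. The arrays lay on 7 slides. DEX and mock arrays shared slides 1 to 3, CHX arrays with and without DEX shared slides 4 and 5, and IAA and mock arrays shared slide 6 (without DEX) and slide 7 (with DEX). In the IAA experiment, slide and DEX cannot be told apart. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3 in Python 3.11.15.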

Results

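Shoot apices of seedlings carrying 35S::WOX1:GR or the control 35S::GFP:GR were profiled on 28 arrays, 1 sample each. WOX1, a homeobox transcription factor that acts in growth of the leaf blade, becomes active in the nucleus once DEX binds the GR domain. GFP:GR apices gave 2 mock and 2 DEX arrays. WOX1:GR apices gave 4 arrays each for mock, DEX, CHX and DEX with CHX, and 2 arrays each for mock then mock, DEX then mock, mock then IAA and DEX then IAA. The share of spots well above background averaged between 68.4% (DEX then IAA) and 74.8% (DEX with CHX) in a group. The first principal component of the genes held 85.7% of the variance and parted the 8 CHX arrays from the other 20, and the second held 3.96% and parted WOX1:GR arrays with DEX from those without in each of the CHX-free and CHX sets.

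WOX1 (AT3G18010, probe A_84_P16455 at chromosome 3, 6161177 to 6161236, TAIR10) had a log2 level of -0.23 ± 0.02 (SD, n = 2) in GFP:GR mock apices and 6.04 ± 0.21 (SD, n = 4) in WOX1:GR mock apices. The difference of 6.27 ± 0.17 (SE), or 77.2-fold, had an adjusted p of 1.1e-15, and a second WOX1 probe (A_84_P854253, chromosome 3, 6162784 to 6162843) differed by 5.95. The arrays do not tell the transgene's RNA from that of the native gene. WOX1 in WOX1:GR apices was at 5.85 ± 0.23 with DEX, a difference from mock of -0.19 ± 0.14 (SE) that was not called (adjusted p = 0.37). CHX raised WOX1 to 7.11 ± 0.09, by 1.07 ± 0.14 (adjusted p = 2.9e-07), and DEX with CHX gave 7.07 ± 0.06. The second probe rose more with CHX, by 1.95 ± 0.21, so the size of this rise depends on the probe. In the IAA experiment WOX1 stood at 6.10 ± 0.33 (mock then mock), 5.81 ± 0.28 (DEX then mock), 6.01 ± 0.34 (mock then IAA) and 5.84 ± 0.22 (DEX then IAA).

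**Figure D1:**
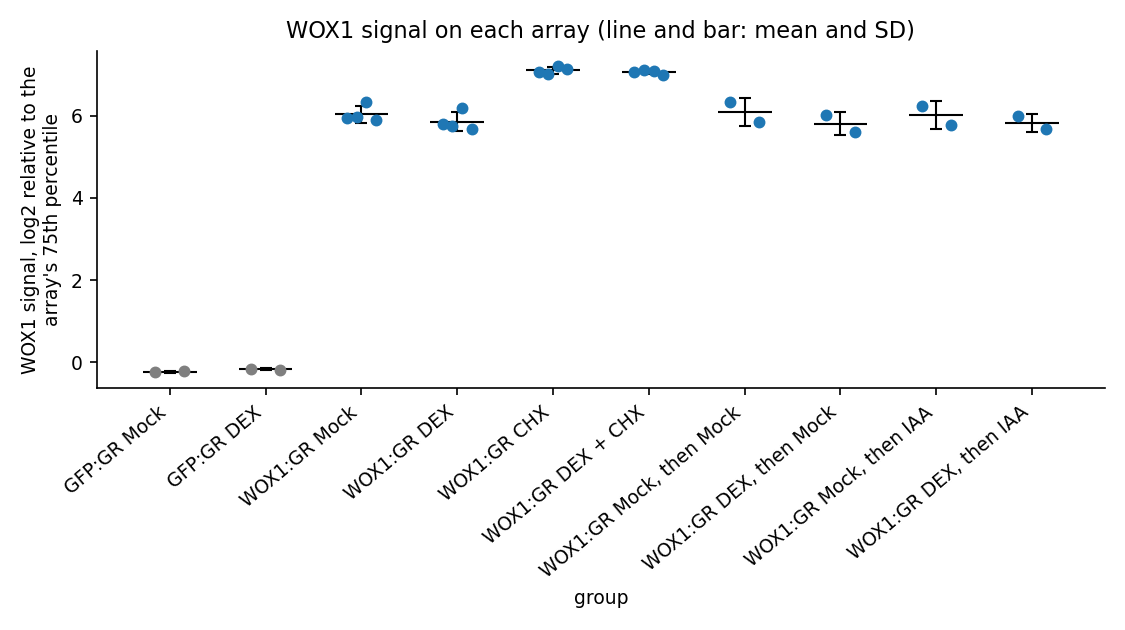
WOX1 signal per array (log2, relative to the array's 75th percentile) in the 10 groups, with points for arrays and a line and bar for mean and SD; GFP:GR is grey and WOX1:GR blue. The 4 GFP:GR arrays lie near -0.2, and the WOX1:GR means lie between 5.81 and 7.11.

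The DEX effect in WOX1:GR asks which genes change when WOX1 is activated. FMO1 (AT1G19250), a flavin monooxygenase that makes N-hydroxypipecolic acid, rose by 4.65 ± 0.88 log2 (SE, n = 4 and 4, adjusted p = 0.0006) and was well above background on 2 of 4 mock arrays. NATA1, an ornithine N-acetyltransferase, rose at least 19.0-fold (0.00017). TAT3, a tyrosine aminotransferase, rose by 3.82 ± 0.83, the thionin gene THI2.1 by 3.41 ± 0.52, the beta-1,3-glucanase gene BGL2 by 3.36 ± 0.47, and the coronatine-induced CORI3 by 3.32 ± 0.31 (adjusted p from 1.5e-07 to 0.0021). The haem oxygenase gene HO4 rose at least 5.07-fold, MPC at least 10.0-fold and the invertase gene CWINV5 at least 3.37-fold, and MEE69 rose by 3.72 ± 0.50. Among the falls, CYP71B22 (AT3G26200) fell at least 64.2-fold (5.8e-11), the oleosin gene OLEO4 at least 16.8-fold, and the abscisic acid receptor gene PYL6 by -4.39 ± 0.33 (1e-08). The peroxidase gene Prx37 fell by -4.36 ± 0.35, the sulphate transporter gene AST91 by -4.23 ± 0.15 (5e-13), PP2-A5 by -4.08 ± 0.59, LHT7 by -4.06 ± 0.80 and AZI1, a lipid-transfer protein gene induced by azelaic acid, by -3.99 ± 0.56. MEE69 was well above background on 2 of 4 mock arrays, Prx37 on 2 of 4 DEX arrays and LHT7 on 1 of 4, so the fitted sizes of these changes rest partly on background signal. Of 21310 genes, 4862 (22.8%) were called, 2075 higher and 2787 lower, 473 and 780 of them by at least 2-fold; 7152 had an unadjusted p under 0.05. The balance depended on the scaling, since the deposited table gave 2228 higher and 2088 lower. With the replicate block 8026 were called, 4854 of these in both fits. On slides 1, 2 and 3 alone, 99.5%, 99.9% and 100.0% of the called genes went the same way, a share that is partly built in because these arrays are in the fit.

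Called auxin, cytokinin and ethylene genes were mostly lower. Of 27 tested SAUR genes, small auxin-up RNAs of growing tissue, 24 fell and 1 (SAUR32, 0.76) rose, or 25 and 1 adjusted over the list alone, with a median of -1.46 (camera adjusted p = 4.61e-17, adjusted p = 0.063 with an estimated correlation). SAUR63 (AT1G29440) fell by -4.14 ± 0.19, SAUR64 by -3.22 ± 0.23 and SAUR67 by -1.73 ± 0.14, and SAUR61 fell at least 6.01-fold. Among 28 Aux/IAA repressors of auxin signalling, 11 fell and 5 rose (12 and 5 adjusted over the list alone, median -0.33, adjusted p = 0.027). IAA19 fell by -1.88 ± 0.17, IAA16 by -1.51 ± 0.15 and IAA13 by -0.80 ± 0.09, IAA6 fell at least 6.30-fold, and IAA33 (2.26) and IAA31 (1.67) rose. Of 16 auxin receptor and ARF genes 3 rose (3 adjusted over the list alone, median 0.20, adjusted p = 0.0191), ARF5 by 1.37 ± 0.13, AFB3 by 0.49 ± 0.10 and ARF16 by 0.31 ± 0.08. In cytokinin metabolism 9 of 18 genes fell and 1 rose (11 and 1 adjusted over the list alone, median -0.40, adjusted p = 0.0012), with LOG8 at -2.44 ± 0.12, LOG5 at -1.69 ± 0.19 and CKX7 at -0.98 ± 0.12. LOG genes make active cytokinin and CKX genes break it down. Of 10 type-A response regulators, which cytokinin induces, 4 fell (5 adjusted over the list alone, median -0.34, bounded -0.52, adjusted p = 0.0352, and 0.0627 with the replicate block). ARR7 fell by -1.58 ± 0.24 and ARR16 by -0.99 ± 0.14. In ethylene synthesis and signalling 5 of 16 genes fell (5 and 1 higher adjusted over the list alone, median -0.36, bounded -0.23, adjusted p = 0.0276), ACO1 by -1.65 ± 0.21. These 5 further calls were lost with an estimated correlation (adjusted p = 0.286 to 0.411 with an estimated correlation).

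Called genes of the upper leaf side and of cell division were mostly higher, and those of ribosomes and the stomatal lineage were lower. Of 9 genes of the adaxial, or upper, leaf side, 6 rose and AS2 fell (7 and 1 adjusted over the list alone, median 0.46, adjusted p = 0.00657). ZPR1 rose by 1.22 ± 0.17, ZPR3 by 0.98 ± 0.20 and PHB by 0.65 ± 0.13, while AS2 fell by -1.18 ± 0.18; ZPR proteins hold back the HD-ZIP III factors to which PHB belongs. Of 25 mitotic genes 16 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.61, adjusted p = 2.02e-07), CYCA2;4 by 1.01 ± 0.20 and the kinase gene AUR2 by 0.75 ± 0.16. In DNA replication 2 of 20 rose (2 adjusted over the list alone, median 0.24, adjusted p = 0.0276), CYCD3;1 by 0.62 ± 0.17 and ICU2 by 0.47 ± 0.15. Of 14 ribosome and nucleolus genes 7 fell (10 adjusted over the list alone, median -0.25, adjusted p = 6.24e-05), FIB2 by -0.79 ± 0.10 and NUC1 by -0.58 ± 0.10. Markers of the stomatal lineage fell in 4 of 9 genes (5 adjusted over the list alone, median -0.73, adjusted p = 0.0191), SPCH, which starts the lineage, by -1.95 ± 0.24. Of 20 jasmonate genes 7 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.75, adjusted p = 0.0191), with LOX2 at 3.23 ± 0.31 and AOS at 1.67 ± 0.28, and of 12 abscisic acid genes 3 rose (3 adjusted over the list alone, median 0.29, adjusted p = 0.0276), COR15A by 2.79 ± 0.48. Each of these 7 calls was lost with an estimated correlation (adjusted p = 0.239 to 0.744 with an estimated correlation). Together with the auxin, cytokinin and ethylene lists, 13 of 36 lists were called.

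The other 23 lists were not called for DEX in WOX1:GR (counts adjusted over the list alone and camera adjusted p in parentheses), although most held called genes. Of 10 genes of the abaxial, or lower, leaf side, 4 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.064), with YAB5 (-1.18 ± 0.09) and YAB3 (-0.62 ± 0.14) lower and ARF3 (1.27 ± 0.21) higher. Of 24 shoot meristem and boundary genes 4 rose and 5 fell (4 and 6, adjusted p = 0.798), with CUC3 at 1.5 ± 0.22 and KNAT6 at -1.52 ± 0.17. Of 24 genes of leaf margin and blade growth 4 rose and 4 fell (4 and 4, adjusted p = 0.869), GRF6 by -3.15 ± 0.26. Among other WOX genes, 1 of 7 rose and 2 fell (1 and 2, adjusted p = 0.63), and WOX4 fell at least 8.48-fold. Of 10 class II TCP genes 3 rose (3, adjusted p = 0.143), TCP10 by 1.06 ± 0.32. In auxin synthesis 1 of 10 rose and 4 fell (1 and 4, adjusted p = 0.445), with YUC5 (above background on 1 of 4 DEX arrays) at -3.78 ± 0.38 and TAA1 at 0.99 ± 0.18. In auxin transport 3 of 15 rose and 3 fell (5 and 4, adjusted p = 0.798). Of 7 GH3 genes 2 rose (3, adjusted p = 0.15), and 0 of 2 LBD genes moved (0, adjusted p = 0.869). Of 18 gibberellin genes 3 rose and 4 fell (4 and 4, adjusted p = 0.869), of 9 brassinosteroid genes 1 rose (1, adjusted p = 0.288), and of 16 salicylate and immune genes 4 rose and 2 fell (4 and 2, adjusted p = 0.43), with PR5 at 1.16 ± 0.17 and CYP81F2 at -3.17 ± 0.62.

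Among the uncalled lists, of 19 cell wall loosening genes 3 rose and 8 fell (3 and 9 adjusted over the list alone, adjusted p = 0.15), with XTH33 at -2.38 ± 0.24 and XTH17 at -2.58 ± 0.53. Of 15 flavonoid genes 3 rose and 1 fell (4 and 1, adjusted p = 0.157), and of 14 glucosinolate genes 3 rose and 2 fell (5 and 2, adjusted p = 0.964), with BCAT4 at 1.52 ± 0.35 and MYB34 at -1.15 ± 0.29. In photosynthesis 2 of 19 fell (2, adjusted p = 0.651), RBCS2B by -0.95 ± 0.16. Heat shock genes held 1 fall in 10 (1, adjusted p = 0.798), HSP18.2 by -0.70 ± 0.13, and clock genes 1 rise in 11 (1, adjusted p = 0.673), ELF3 by 0.23 ± 0.07. The only tested root marker, COBL9, above background on 1 of 4 DEX arrays, fell by -2.63 ± 0.50 (1, adjusted p = 0.142), and the flowering shoot marker FUL fell by -1.0 ± 0.24, 1 of 5 (1, adjusted p = 0.451). In vascular tissue 1 of 9 rose and 2 fell (1 and 2, adjusted p = 0.869), with SUC2 at -0.77 ± 0.17, and among 7 trichome markers 1 rose and 1 fell (1 and 1, adjusted p = 0.891), GL3 by 1.31 ± 0.34 and GL1 by -0.81 ± 0.26. Of 4 seed storage genes, 0 were called (0, adjusted p = 0.798).

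**Figure D2:**
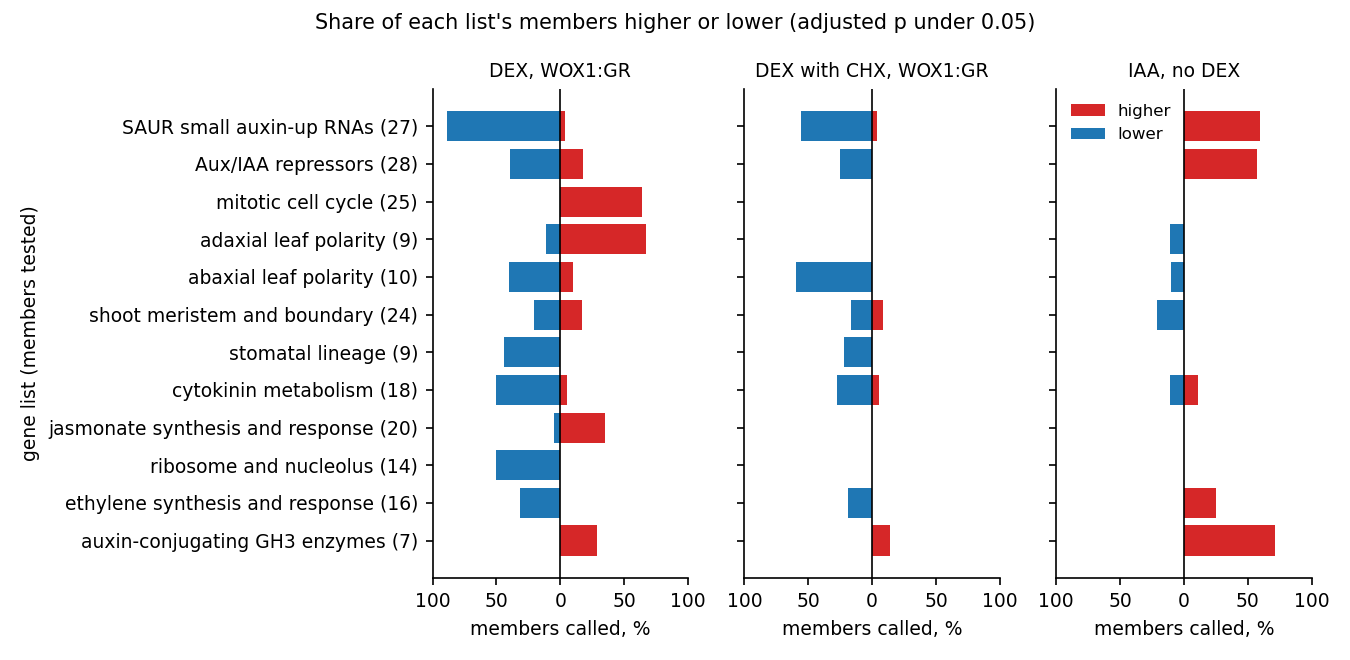
Percent of the tested members of 12 gene lists called higher (red, right) or lower (blue, left) for DEX in WOX1:GR, DEX with CHX and IAA without DEX. SAUR genes go left in the first 2 panels (24 and 15 of 27 lower) and right with IAA (16 of 27 higher).

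In GFP:GR apices, which test DEX and the GR domain without WOX1, 0 genes were called by limma. At an unadjusted p under 0.05 there were 127 genes, against 1065.5 by chance, and the smallest adjusted p was 0.094. Mock and DEX arrays of the same GFP:GR line, which also share a slide, correlated at 0.711 in their deviations from group means. The main fit leaves this pairing out, so the shortfall against chance is not read as a result. The replicate block and the slide block also gave 0 calls, the former with 467 genes at unadjusted p under 0.05. Without 1 array the count was 4 (mock replicate 1), 8 (mock replicate 2) or 1 (DEX replicate 1), where the lone array is assumed to vary like the other groups. The SAUR genes had a median effect of -0.02 there. Photosynthesis genes (median -0.22, camera adjusted p = 1.32e-05), ribosome and nucleolus genes (-0.09, 0.00168), seed storage genes (-0.84, 0.00314) and heat shock genes (-0.34, 0.0322, and 0.136 with the replicate block) were called as lists, with 0 members called over all genes and 1 seed storage gene adjusted over the list alone. All 4 were lost with an estimated correlation (adjusted p = 0.968 to 0.989 with an estimated correlation), and ribosome and nucleolus genes changed sign under quantile normalization (0.04).

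The difference between the constructs was tested directly. FMO1 had a fitted difference of 7.28 ± 1.52, higher in WOX1:GR than in GFP:GR (adjusted p = 0.007). GFP:GR DEX arrays held no FMO1 signal well above background, so this value is not a size of change. AST91 differed by -4.21 ± 0.27 and Prx37 by -4.25 ± 0.61. HO4 (adjusted p = 5.4e-05) and NATA1 (0.048) also passed, but of these 4 groups only WOX1:GR DEX held HO4 above background, and NATA1 was below it on all WOX1:GR mock arrays and on 1 of 2 arrays in each GFP:GR group, so no size is given. CYP71B22 differed by -7.92 ± 0.69, a fitted value because WOX1:GR DEX arrays were below background. MPC, TAT3, BGL2 and LHT7, among the largest DEX changes, did not pass this test (adjusted p = 0.055, 0.16, 0.12 and 0.069). SAUR genes differed in 10 of 27 members, all lower (21 lower and 1 higher adjusted over the list alone, median -1.47, camera adjusted p = 9.29e-19, adjusted p = 0.0425 with an estimated correlation), SAUR63 by -4.20 ± 0.33. In cytokinin metabolism 4 were lower (6 and 1 higher adjusted over the list alone, adjusted p = 0.000227), and in the Aux/IAA list 5 were lower and 3 higher (10 and 5, adjusted p = 0.0121), IAA19 by -1.94 ± 0.30. Mitotic genes had a median of 0.61 with 0 members called (7.87e-06), and adaxial genes held ZPR1 at 1.37 ± 0.30 and AS2 at -1.27 ± 0.32 (0.00811). In all 15 lists were called, 14 of which were lost with an estimated correlation (adjusted p = 0.23 to 0.698 with an estimated correlation); stomatal, ARF and abaxial lists were also lost with the replicate block (0.0547 to 0.0577). Of 21310 genes 937 were called, 335 higher and 602 lower (431 and 530 under normexp), with 2775 under the replicate block. Without GFP:GR mock replicate 1, mock replicate 2 or DEX replicate 2 the counts were 522, 519 and 518.

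The DEX effect with CHX asks which changes occur while protein synthesis is blocked. SAUR63 fell by -5.33 ± 0.19 (adjusted p = 4.1e-13), SAUR64 by -4.30 ± 0.23, SAUR15 by -4.58 ± 0.36 and SAUR14 by -4.13 ± 0.32. CO (CONSTANS, AT5G15840), a regulator of flowering, fell by -4.64 ± 0.22, AZI1 by -4.39 ± 0.56, LHT7 by -3.97 ± 0.80, and bZIP3, SAUR62 and PDLP4 fell at least 8.91-, 6.45- and 5.22-fold. With DEX and CHX, SAUR15 and SAUR14 were well above background on 1 of 4 arrays, CO on 2 of 4 and SAUR63 on 3 of 4. The fitted sizes of these falls therefore rest partly on background signal. FMO1 rose by 3.08 ± 0.88 (0.033), GLP9 by 2.35 ± 0.68, WRKY55 by 2.25 ± 0.29 (1.9e-05), WRKY50 by 1.88 ± 0.50 and RLK1 by 1.73 ± 0.40. MYB62 rose by 1.70 ± 0.52, RLP38 by 1.57 ± 0.39, ACT12 by 1.53 ± 0.40, MES9 by 1.52 ± 0.34 and the cytokinin synthesis gene IPT7 by 1.70 ± 0.45. Without CHX, WRKY55 showed no such rise, at -5.35 ± 0.37 in mock and -5.31 ± 0.51 with DEX. GLP9, ACT12 and PDLP4 were well above background on at most 1 of 4 arrays in each of these 2 groups. No DEX effect without CHX was therefore measured for these genes. Of 21310 genes 1727 (8.10%) were called, 629 higher and 1098 lower (771 and 914 in the deposited table), and 3264 with the replicate block.

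Of the SAUR genes, 15 of 27 fell with CHX and 1 rose (21 and 1 adjusted over the list alone, median -1.65, bounded -2.04, camera adjusted p = 1.43e-26, adjusted p = 0.00828 with an estimated correlation). Abaxial genes fell in 6 of 10 (8 adjusted over the list alone, median -0.45, adjusted p = 2.27e-05, adjusted p = 0.0297 with an estimated correlation), YAB5 by -0.99 ± 0.09, KAN1 by -1.15 ± 0.25 and YAB1 by -0.61 ± 0.15. Cytokinin metabolism fell in 5 and rose in 1 of 18 (5 and 3, adjusted p = 0.00462), LOG8 by -1.88 ± 0.12, and Aux/IAA genes fell in 7 of 28 (8 and 2 higher, adjusted p = 0.0066), IAA16 by -1.11 ± 0.15. Vascular markers fell in 3 of 9 (3, adjusted p = 0.031), SUC2 by -1.64 ± 0.17. The calls for flowering (0.0313), stomatal (0.0339) and auxin synthesis genes (0.0373) were lost with the replicate block (0.0528 to 0.0726), and the last 6 lists all were with an estimated correlation (adjusted p = 0.252 to 0.588 with an estimated correlation). Mitotic (median -0.05), adaxial (0.03), jasmonate (0.32) and ribosome genes (-0.07), called without CHX, had 0 called members here and adjusted p from 0.366 to 0.901. CHX alone lowered all mitotic genes, and the adaxial and ribosome lists were also called for CHX alone, as given below. The absence of calls here therefore does not show that these responses need new protein. Of the DEX effects without CHX, 961 genes were called the same way with CHX (273 up, 688 down; 61.2 and 143.6 by chance) and 33 opposite; across genes, which are not independent replicates, r was 0.541 and rho 0.445. With the replicate block 1830 were called alike. Of the 4862 genes 80.2% went the same way with CHX.

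**Figure D3:**
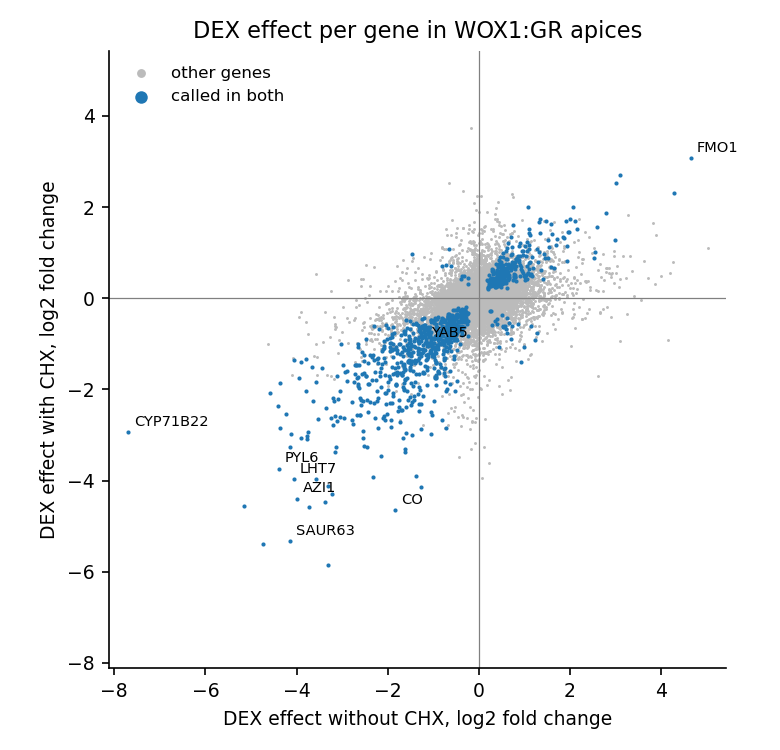
DEX effect in WOX1:GR without CHX (x, log2) against that with CHX (y, log2), 1 point per gene, with genes called in both in blue. SAUR63 lies far down on both axes (-4.14 and -5.33), and 961 genes were called the same way in both.

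The difference of the DEX effects with and without CHX was called for 1083 genes (537 higher, 546 lower; 694 and 581 under quantile normalization, 357 and 427 in the deposited table; 3257 with the replicate block). FIB2, a fibrillarin gene, differed by 0.69 ± 0.15. CYP71B22 (4.77 ± 0.56), UPB1 (-4.32 ± 0.79) and MLS (3.4 ± 0.32) each had 1 group below background on all arrays, while WOX4 (3.6 ± 0.38), SHN3 (-4.02 ± 0.80) and PDLP4 (-4.01 ± 0.56) had more, so their fitted values partly reflect absent signal. WOX4 was not well above background on any CHX array, with or without DEX, so no DEX effect with CHX was measured for it. As lists, mitotic genes differed downward (3 of 25, 12 adjusted over the list alone, median -0.72, adjusted p = 4.57e-09), with CDKB1;2 at -0.92 ± 0.23, ribosome genes upward (2 and 3, adjusted p = 0.000592), adaxial genes downward (3 and 3, adjusted p = 0.0085), with PHB at -0.91 ± 0.18, TCP genes downward (1 and 1, adjusted p = 0.0169), type-A regulators upward (2 and 2, adjusted p = 0.0218), with ARR5 at 1.73 ± 0.30, and ARF genes downward (1 and 1, adjusted p = 0.0229), ARF5 at -1.19 ± 0.18. All 6 were lost with an estimated correlation (adjusted p = 0.257 to 0.592 with an estimated correlation). Baseline levels with and without CHX were not matched, so these list differences do not show a need for new protein.

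CHX itself changed most genes. The auxin glucosyltransferase gene UGT84B1 rose at least 2789-fold (adjusted p = 1.1e-18), the lipase gene GLIP1 at least 1389.9-fold, ARI12 by 12.01 ± 0.68 and BGLU27 by 11.26 ± 0.56. CYP96A5, PUM13, sks8 and ABCG28 rose at least 2034.8-, 846.6-, 801.9- and 711.1-fold, EM1 by 10.84 ± 0.66 and BAP2 by 10.80 ± 0.52. ARI12 and BGLU27 were well above background on 1 of 4 mock arrays, and EM1 and BAP2 on 2 of 4, so these fitted sizes rest largely on background signal. GRP5 fell by -9.99 ± 0.29, though it was above background on 2 of 4 CHX arrays and its other probes fell less (-5.36 at the smallest), the tonoplast aquaporin gene TIP2 fell by -9.73 ± 0.17 (1.4e-19), XTH7 by -8.84 ± 0.17 and the glucosinolate gene CYP83A1 by -8.35 ± 0.30, with CYP79F1, IPMI1 and MYB29 of the same pathway down at least 194.2-, 153.7- and 112.1-fold. ADS1 fell at least 253.6-fold, GASA6 by -9.36 ± 0.22 (-5.11 at its other probe) and ELP by -8.73 ± 0.42. All 25 mitotic genes fell (25 adjusted over the list alone, median -3.02, adjusted p = 4.14e-06), CYCA1;1 by -7.06 ± 0.27, as did all 19 photosynthesis genes (19, median -3.55, adjusted p = 5.4e-05). Of 24 meristem genes 20 fell and 1 rose (20 and 1, median -2.19, adjusted p = 0.000129), STM (above background on 1 of 4 CHX arrays) by -5.31 ± 0.11, and of 16 salicylate and immune genes 14 rose and 1 fell (14 and 1, median 3.70, adjusted p = 0.00379), PBS3 by 8.68 ± 0.63 and NPR1 by 4.22 ± 0.17. SAUR genes fell in 23 of 27 (23, median -2.06, bounded -2.04, adjusted p = 0.00199). DNA replication, leaf margin, ribosome, adaxial, abaxial, glucosinolate, stomatal and vascular lists were also called, mostly lower (0.000129 to 0.0446, the vascular list 0.0685 with the replicate block). All 13 list calls were lost with an estimated correlation (adjusted p = 0.518 to 0.548 with an estimated correlation). Of 21310 genes 18324 (86.0%) were called, 8740 higher and 9584 lower (9134 and 8936 in the deposited table), and 17482 with slide as a random block, since CHX and mock arrays share no slide. Under the deposited table the median of all genes moved from -0.09 to 0.03, by 0.117.

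IAA without DEX, the auxin response, raised auxin-response genes. IAA5 rose by 6.69 ± 0.69 (SE, n = 2 and 2, adjusted p = 3.3e-06), IAA29 by 6.08 ± 0.54, and the conjugating enzyme genes GH3.3, GH3.2 and GH3.1 by 5.16 ± 0.32 (4.5e-09), 5.06 ± 0.45 and 4.87 ± 0.47. The ethylene synthesis gene ACS4 rose at least 21.0-fold, CYP78A10 at least 25.6-fold and RALFL18 at least 24.2-fold, NCED5 of abscisic acid synthesis rose by 5.10 ± 0.61 and SAUR10 by 5.01 ± 1.00. MYB48 fell at least 5.59-fold, GLTP2 at least 5.06-fold, RLP19 at least 3.59-fold, GIS2 at least 2.11-fold and the trans-zeatin synthesis gene CYP735A2 at least 2.09-fold. The nicotianamine synthase gene NAS1 fell by -2.78 ± 0.35, the nitrate transporter gene NRT1.5 by -3.10 ± 0.58, BGLU47 by -3.26 ± 0.47, CRK30 by -2.74 ± 0.31 and PYL6 by -2.65 ± 0.47. Of 21310 genes 766 were called, 401 higher and 365 lower, and 1494 with the replicate block. On only the groups compared the count was 196, and without mock then mock replicate 1 or 2 or mock then IAA replicate 1 or 2 it was 426, 386, 398 and 438.

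By lists, 16 of 28 Aux/IAA genes rose (18 adjusted over the list alone, median 1.01, camera adjusted p = 1.17e-33, adjusted p = 1.47e-05 with an estimated correlation), IAA19 by 4.73 ± 0.24. SAUR genes rose in 16 of 27 (22 adjusted over the list alone, median 1.61, adjusted p = 3.87e-26, adjusted p = 0.00229 with an estimated correlation), SAUR24 by 2.30 ± 0.29, and GH3 genes in 5 of 7 (6 and 1 lower, median 3.96, adjusted p = 1.87e-19). Type-A response regulators fell in 7 of 10 (7, median -1.01, bounded -1.26, adjusted p = 7.04e-12, adjusted p = 0.00173 with an estimated correlation), ARR6 by -2.62 ± 0.35 and ARR4 by -1.31 ± 0.16. Ethylene (4 rose, adjusted p = 4.85e-07), abscisic acid (3 rose, adjusted p = 0.000114) and LBD genes (1 of 2 rose, median 1.80, bounded 0.69, both with 1 group below background, adjusted p = 0.00547) kept their calls with an estimated correlation (adjusted p = 0.00229 to 0.0438 with an estimated correlation), ABI1 rising by 1.3 ± 0.19. Auxin transport (3 rose, 1 fell, adjusted p = 7.56e-06), meristem and boundary (5 fell, adjusted p = 4.09e-05), with CUC2 at -1.35 ± 0.26, glucosinolate (1 fell, adjusted p = 0.000162), with MYB29 at -2.28 ± 0.33, and seed storage (0.00315), leaf margin (0.0141), stomatal (0.0145), brassinosteroid (0.0172), flowering (0.0348) and auxin synthesis (0.0427) lists were lost with it (adjusted p = 0.116 to 0.496 with an estimated correlation). The last 3 of these were also lost with the replicate block (0.0747 to 0.0757). Against the DEX effect in WOX1:GR, 251 genes were called the same way with IAA (80 up against 39.0 by chance, 171 down against 47.7). Opposite calls numbered 149, of which 46 were higher with DEX and lower with IAA (35.5 by chance). The other 103 were lower with DEX and higher with IAA (52.4 by chance). Both kinds of overlap thus exceeded the counts for independent calls, and across genes r was 0.123 and rho 0.210. The 2 comparisons come from 1 fit with 1 spread per gene, so genes of low spread are more readily called in both. The excess alone therefore does not show a shared response. With the replicate block 592 were called the same way and 300 opposite. Without mock then mock replicate 1 or 2, or mock then IAA replicate 1 or 2, the same-way counts were 131, 126, 130 and 127 and the opposite counts 92, 84, 80 and 99.

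After DEX, IAA raised IAA29 by 7.53 ± 0.54 (2.5e-08), IAA5 by 6.72 ± 0.69 and ACS4 at least 30.2-fold, and lowered BGLU47 by -3.10 ± 0.47, MYB48 at least 9.82-fold and CYP707A4 at least 5.29-fold. SAUR genes rose in 23 of 27 (25 and 1 lower adjusted over the list alone, median 2.96, bounded 2.55, adjusted p = 4.82e-66, adjusted p = 1.71e-05 with an estimated correlation), SAUR65 by 5.47 ± 0.45 and SAUR64 by 4.13 ± 0.32, and Aux/IAA genes in 19 of 28 (21, median 1.60, adjusted p = 2.52e-54), IAA19 by 5.84 ± 0.24. In all, 12 lists and 606 genes were called (393 higher, 213 lower; 1094 with the replicate block; 60 on only the groups compared). Of the 12, auxin transport, leaf margin, cell wall, meristem and LBD genes were lost with an estimated correlation (adjusted p = 0.0504 to 0.329 with an estimated correlation). Without DEX then mock replicate 1 or 2 or DEX then IAA replicate 1 or 2, 376, 340, 350 and 364 genes were called.

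The difference of the IAA effects was called for 3 genes, all higher after DEX: BEE1 (2.88 ± 0.44, adjusted p = 0.014), SAUR63 (2.76 ± 0.38, 0.0063) and AT5G62260 (1.40 ± 0.19, 0.0063), the last named after its values were seen because it has no symbol. The SAUR63 log2 levels were -0.50 in mock then mock, -4.65 in DEX then mock, 0.79 in mock then IAA and -0.60 in DEX then IAA. SAUR genes as a list differed by a median of 0.94 (1 called, 7 adjusted over the list alone; 2.16e-29, adjusted p = 0.0049 with an estimated correlation), Aux/IAA genes by 0.28 (0 called; 3.19e-07, adjusted p = 0.0302 with an estimated correlation) and abscisic acid genes by -0.26 (0.00138, adjusted p = 0.0176 with an estimated correlation). Seed storage, ribosome, type-A, photosynthesis, ethylene and mitotic lists were lost (adjusted p = 0.123 to 0.918 with an estimated correlation). The normexp and quantile fits called 12 (10 higher, 2 lower) and 15 (9 and 6), the replicate block 25 and the slide block 53. Only the groups compared gave 6. Without mock then mock replicate 1 or 2, DEX then mock replicate 1 or mock then IAA replicate 1 the count was 0, 1, 11 and 1, and 450 genes had an unadjusted p under 0.05.

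**Figure D4:**
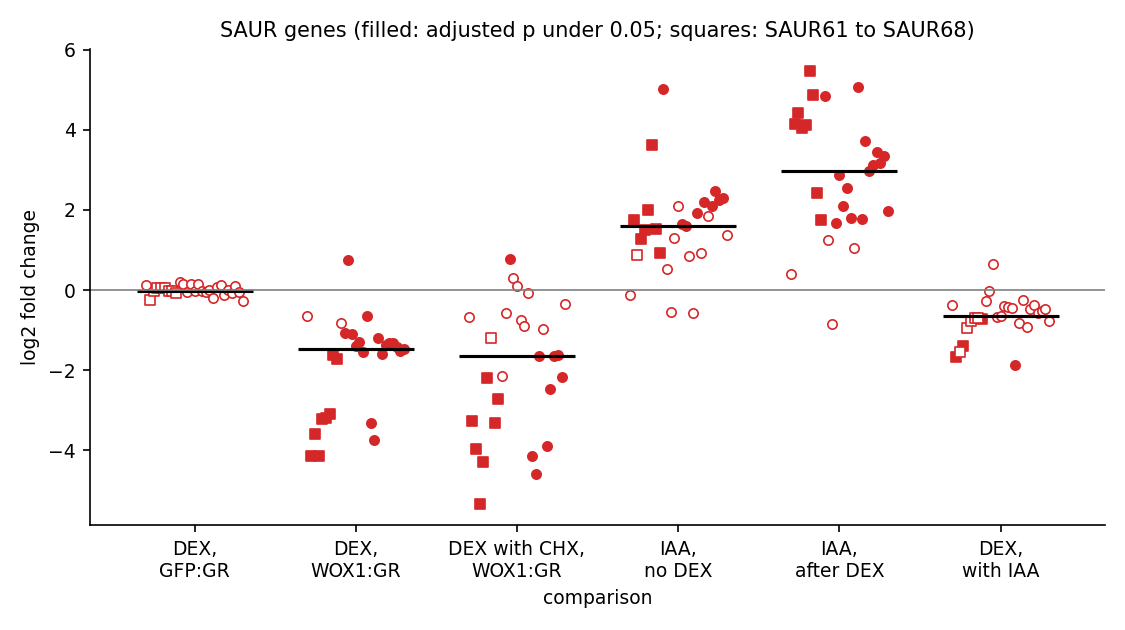
log2 fold changes of 27 SAUR genes in 6 comparisons; filled points have an adjusted p under 0.05, squares are SAUR61 to SAUR68 and the black line is the median. The medians are -0.02 for DEX in GFP:GR, -1.46 for DEX in WOX1:GR and -1.65 with CHX, and 1.61 and 2.96 for IAA without and after DEX.

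In the IAA experiment, DEX then mock against mock then mock lay on different slides. TAT3 rose at least 12.9-fold, THI2.1 at least 22.7-fold and NATA1 at least 11.8-fold, CYP71B22 fell at least 32.9-fold and LHT7 at least 24.2-fold. SYNC1 fell by -6.33 ± 1.90 with a DEX then mock level of -3.18 ± 8.47 (SD, n = 2) and other probes at up to -0.11. SAUR genes fell in 18 of 27 and 1 rose (22 and 1 adjusted over the list alone, median -1.52, adjusted p = 2.83e-17, adjusted p = 0.0598 with an estimated correlation), and adaxial genes rose in 5 of 9 and fell in 1 (7 and 1, adjusted p = 0.00167, adjusted p = 0.486 with an estimated correlation), ZPR1 by 1.40 ± 0.25. In all 9 lists were called, the other 7 being mitotic, ribosome, cytokinin metabolism, stomatal, ARF, DNA replication and jasmonate lists, of which none held with an estimated correlation (adjusted p = 0.334 to 0.728 with an estimated correlation). Of 21310 genes 2507 (11.8%) were called, 1029 higher and 1478 lower, with 5468 under the replicate block, 607 with slide as a random block and 570 on only the groups compared. Without mock then mock replicate 1 or 2, or DEX then mock replicate 2, they were 988, 1504 and 1133. Against the within-slide DEX effect of the other experiment, 2353 genes were called the same way (100.2 up and 193.3 down by chance; 942 and 1411 found), 0 opposite, with r 0.870 and rho 0.823 across genes, and 4928 with the replicate block. Without mock then mock replicate 1 or 2, or DEX then mock replicate 1 or 2, the count was 957, 1425, 1520 and 1110. Genes lower in all 3 of the DEX comparisons (without CHX, with CHX, in the IAA experiment) numbered 552 and those higher 169 (9.96 and 2.96 if independent). Those lower included CYP71B22 (at least 64.2-fold, -2.94 ± 0.40 and at least 32.9-fold), AT2G41870 (at least 16.1-fold, -4.56 ± 0.29 and at least 10.9-fold), AT4G15680 (-4.73 ± 0.39, at least 23.7-fold and at least 7.99-fold), LHT7 (-4.06, -3.97 and at least 24.2-fold), AT5G61590 (-3.32 ± 0.41, -5.85 ± 0.41 and -4.35 ± 0.59) and SAUR62 (-3.58 ± 0.59, at least 6.45-fold and at least 8.06-fold). AT4G15680 and SAUR62 were above background on 1 of 4 DEX arrays. Also lower were AZI1 (-3.99, -4.39 and -4.47 ± 0.80), PYL6 (-4.39, -3.74 ± 0.33 and -4.56 ± 0.47), SAUR15 (-3.73 ± 0.36, -4.58 ± 0.36 and -3.95 ± 0.51) and SAUR63 (-4.14, -5.33 and -4.15 ± 0.27). SAUR15 was well above background on 3 of 4 DEX, 1 of 4 DEX with CHX and 1 of 2 DEX then mock arrays. SAUR63 was so on 3 of 4 DEX with CHX arrays.

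With IAA present, DEX then IAA against mock then IAA called 998 genes (386 higher, 612 lower; 3049 with the replicate block, 225 with slide as a random block and 0 on only the groups compared). DR4 rose by 4.60 ± 0.76 (0.00076), HMT3 by 3.67 ± 0.88 and TAT3 at least 9.41-fold, and CYP71B22 and UGT76B1 fell at least 13.2- and 15.9-fold. SAUR genes fell in 4 of 27 (5 adjusted over the list alone, median -0.65; 8.68e-05, adjusted p = 0.55 with an estimated correlation). The other 9 list calls were lost too (adjusted p = 0.43 to 0.878 with an estimated correlation). Without mock then IAA replicate 1 or DEX then IAA replicate 2, the count was 370 and 437.

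Before DEX, WOX1:GR and GFP:GR apices differed in 1 gene, WOX1 itself, while 944 had an unadjusted p under 0.05 and the slide block gave 3 calls. Flavonoid genes were lower in WOX1:GR by a median of -1.12, with 0 members called over all genes and 12 adjusted over the list alone (camera 3.09e-16, adjusted p = 0.443 with an estimated correlation). Jasmonate (-0.46, 0.000162), heat shock (0.43, 0.00289), Aux/IAA (-0.14, 0.012), meristem (-0.10, 0.0474) and leaf margin genes (-0.14, 0.0474) were called too, with 0 members called over all genes, and lost (adjusted p = 0.701 with an estimated correlation). The normexp fit called 2 genes, 1 higher and 1 lower. Without GFP:GR mock replicate 1 or 2 there were 3 and 10.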

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

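The tests of cross-hybridisation, DEX alone, dissection, slides, scaling and the IAA level were chosen only after the result was seen, as was parting the experiments both without and with CHX. Only the shares over all splits of the arrays were chosen before.

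SAUR genes fell with DEX in WOX1:GR, with a median of -1.46 over 27 genes. Binding of near-identical SAUR61 to SAUR68 RNAs to each other's probes does not account for the whole pattern, since the 19 genes outside that cluster had a median of -1.318 (upper quartile -1.07), with 16 called lower, against -3.21 and 8 of 8 inside it. Binding among the RNAs and probes of these 19 genes was not tested, so their values may not be separate results. DEX or the GR domain alone is argued against by the GFP:GR median of -0.01964 (quartiles -0.05 to 0.09). Chance differences in dissection between arrays are argued against because the highest SAUR median of the 5 slides with DEX and control arrays was -1.456, the others being -1.52, -1.59, -1.78 and -1.57. A change in the cell make-up of the apex driven by WOX1 itself may contribute and stays open, beside a direct or indirect effect of WOX1 on these genes.

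CHX changed most genes, 86.0% of those tested, while CHX and mock arrays lay on different slides. Slide differences as the whole cause are argued against by the median absolute difference between slides within WOX1:GR mock arrays, 0.2576, and within CHX arrays, 0.197, against a median absolute CHX effect of 1.29. A scaling factor per array as the whole cause is argued against because, among 18013 genes well above background on every mock and CHX array, 54.9% were changed at least 2-fold and no single shift of all genes brought this below 54.05%. Slide differences may still shift single genes with small changes, and a change in the total RNA per cell was not measured, so the changes are relative to the 75th percentile.

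The DEX effect in the IAA experiment, 2507 genes, compares arrays on slides 6 and 7. Of these genes, 99.52% went the same way in the separate experiment in which DEX and mock arrays shared slides. Slide differences as the main cause are argued against by this, and slides may still add to the count for single genes, as 607 genes were called with slide as a random block.

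Each count of splits below includes the real split. For DEX, 2 of 35 splits gave at least 4862 genes, the real one and 1 other, so chance is not excluded by this count alone. The other was the split of experiment 1 from experiment 2, with 4921, which points to a structure of the arrays. Experiment 1 lay on slides 1 and 2 and experiment 2 on slide 3, so sampling and slide cannot be told apart in it. The split by line gave 1, and the DEX effect blocked by line and experiment gave 8026. Among the 8 splits that part the 4 pairs as the real one does, the highest other count was 1. For DEX with CHX, 2 of 35 splits gave as many as 1727, the experiment split 2630 and the line split 523. The blocked value was 3264, and the highest other among splits parting 4 pairs was 2. For CHX, 1 of 35 splits, the real one, gave as many as 18324 (highest other 6809), a share under 0.05. Among the 8 splits that part all 4 pairs, too few for such a share, the highest other was 1. CHX and mock arrays share no slide, so the real split also parts slides, and this count alone cannot tell CHX from slide. For the difference of DEX effects by CHX, 3 of 100 gave as many as 1083 (highest other 1703), and this leaves a structure of the arrays open. Of the 2 others, 1 kept DEX and mock parted as in the real split (1703) and 1 parted the experiments without CHX (1095). Parting the experiments both without and with CHX gave 2745 or 5526, by orientation. The blocked value was 3257, and among the 8 draws that part all 8 pairs the highest other was 90. For the overlap 1 of 100, the real one, gave as many as 961 (highest other 0). This count decides nothing, since 0 of the 99 others called at least 100 genes in both comparisons. Parting the experiments the same way in both gave an overlap of 975, so the size of the overlap alone does not exclude a structure of the arrays, and the blocked overlap was 1830. For called lists, 1 of 35 splits gave as many as 13 with DEX (highest other 11). All 13 calls were lost with an estimated correlation (adjusted p = 0.063 to 0.744 with an estimated correlation), a split with 0 genes called still gave 11 lists, and the 8 splits that part all 4 pairs (highest other 9) are too few for a share under 0.05, so no list call rests on this count. Chance is not excluded for 8 lists with DEX and CHX (7 of 35, highest other 11), 13 with CHX (8 of 35, highest other 16) and 6 for the difference (39 of 100, highest other 11).

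Single arrays lay far from the other 3 of their group in 7 of 132 sets of named genes, 5.3%, where chance gives about 5%. In WOX1:GR DEX, FMO1 was at -4.92 in replicate 1 (others -1.34 to -1.10), HO4 at -5.24 in replicate 1 (-4.79 to -4.73) and AST91 at -4.72 in replicate 3 (-4.16 to -4.12). In WOX1:GR mock, BGL2 was at -7.03 in replicate 1 (-5.24 to -5.11), ARI12 at -6.66 (-8.43 to -8.17), BGLU27 at -7.37 (-8.74 to -8.67) and WOX1 at 6.34 (5.90 to 5.96) in replicate 3.

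DEX effects differed between the constructs in 937 genes. FMO1 differed by 7.28, NATA1 by 5.13, HO4 by 4.38, CYP71B22 by -7.92, Prx37 by -4.25 and AST91 by -4.21. Of these, only AST91 was well above background on every array of the 4 groups, and among these groups HO4 was above it in WOX1:GR DEX alone, NATA1 on 0 of 4 WOX1:GR mock arrays, FMO1 on 0 of 2 GFP:GR DEX arrays and CYP71B22 on 0 of 4 WOX1:GR DEX arrays, so these fitted differences are not sizes of change. DEX effects differed with and without CHX in 1083 genes. CYP71B22 differed by 4.77, WOX4 by 3.6, MLS by 3.4, UPB1 by -4.32, SHN3 by -4.02 and PDLP4 by -4.01, all 6 with at least 1 group below background on every array. IAA effects differed with and without DEX in 3 genes, BEE1 by 2.88 and SAUR63 by 2.76 among them. Among 3737 tested probes matched to no single gene, 257 (6.88%) were called with DEX in WOX1:GR, 113 higher and 144 lower, against 0 called by limma in GFP:GR, where 58 had an unadjusted p under 0.05.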

How the results depend on the processing

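The fits on 1 experiment or 1 line were chosen only after the data were seen, and all other settings before. Counts within 1.5 times the reported count under an alternative are not listed, and the cause of a move was not tested unless fewer arrays were fitted. With the replicate block, DEX in WOX1:GR went from 4862 to 8026 genes, DEX by construct from 937 to 2775, DEX with CHX from 1727 to 3264, DEX by CHX from 1083 to 3257, IAA from 766 to 1494, IAA after DEX from 606 to 1094, the IAA difference from 3 to 25, DEX in the IAA experiment from 2507 to 5468, and DEX with IAA from 998 to 3049. The overlaps rose to 1830 (without and with CHX), 592 alike and 300 opposite (DEX and IAA) and 4928 (both experiments). The slide as a fixed block gave 7670, 2563, 3242, 3140, 1558, 1185 and 53 in the order DEX, by construct, DEX with CHX, DEX by CHX, IAA, IAA after DEX and the IAA difference, and 3 for WOX1:GR against GFP:GR, while slide as a random block gave 607 and 225 for DEX in the IAA experiment and with IAA. Only the groups compared gave 196 (IAA), 60 (IAA after DEX), 6 (IAA difference), 570 (DEX in the IAA experiment) and 0 (DEX with IAA). Normexp and quantile fits gave 12 and 15 for the IAA difference, and for WOX1:GR against GFP:GR normexp gave 2 and the mean of the probes 2. Fits with fewer arrays gave 2234 (experiment 2), 1515 (line 1) and 1932 (line 2) for DEX. DEX with CHX gave 967, 995, 557 and 628 (experiments 1 and 2, lines 1 and 2), DEX by CHX 374, 257, 53 and 102, and the overlap without and with CHX 523, 518, 308 and 366. Of 432 list tests 121 were called, and 20 with an estimated correlation.

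Leaving out 1 array gave 3742 to 4574 genes for DEX, 0 to 8 for DEX in GFP:GR, 518 to 1020 by construct, 1378 to 1561 for DEX with CHX, 762 to 1126 for DEX by CHX, 386 to 438 for IAA, 340 to 376 for IAA after DEX, 0 to 11 for the IAA difference, 988 to 1708 and 370 to 901 for DEX in the IAA experiment and with IAA, and 1 to 10 for WOX1:GR against GFP:GR. The overlaps ranged over 828 to 934 (without and with CHX), 126 to 253 alike and 80 to 151 opposite (DEX and IAA), and 957 to 2282 (both experiments). Counts for CHX stayed between 15190 and 18974 in the settings run. Of 734 called gene values, 405 lost their call in at least 1 setting, and 12451 of 14157 values in other settings kept it. Signs turned for SAUR20 in DEX by CHX under normexp (0.126, from -2.52), for ribosome and nucleolus genes in GFP:GR under quantile normalization (0.0406), and for WOX1 with DEX and CHX, not called, in line 1 (0.056) and in the deposited table (0.013). Signal over background limits the folds given as bounds.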

Other observations

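The neighbouring loci AT4G15660 to AT4G15700, the comparison of falls with rises and its other scalings were chosen only after the result was seen. Without and with CHX, DEX lowered AT4G15680 by -4.73 ± 0.39 log2 and at least 23.7-fold, AT4G15700 by -2.21 ± 0.29 and -2.18 ± 0.29, and AT4G15670 by -1.04 ± 0.32 and -2.49 ± 0.32. AT4G15690 fell by -1.88 ± 0.36 without CHX, and with both DEX and CHX it was not well above background on any array. AT4G15660 was not called without CHX (-0.54 ± 0.51, adjusted p = 0.512) and was below background in both CHX groups. In GFP:GR all 5 lay between -0.15 and 0.03. Binding of RNA from 1 locus to the probes of its neighbours was not tested, so the 5 values may not be separate results.

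Of the genes that DEX lowered at least 2-fold, 384 of 780 (49.2%) were called lower again with CHX, and of those raised at least 2-fold 65 of 473 (13.7%) were called higher again. Among genes well above background on every CHX array the shares were 322 of 604 (53.3%) and 53 of 338 (15.7%), a gap of 37.63 percentage points, so low signal with CHX does not remove it. The gap was 42.91 under normexp, 34.58 under quantile normalization and 34.47 in the deposited table, although the balance of rises and falls with CHX moved in the last. It was not computed with the replicate block. That block took the calls for DEX with CHX from 629 to 1448 higher and from 1098 to 1816 lower. That falls depend less on new protein than rises is a hypothesis drawn from this gap, and no separate test of it was run. The gap may also reflect the baseline levels under CHX, which were not matched.

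The SAUR genes with DEX and IAA had a median DEX effect of -0.6469, against -1.52 without IAA. Whether added IAA brings these genes to the same level with and without DEX stays open. DEX and mock arrays with IAA lay on different slides, 4 of 27 genes were called, only the groups compared gave 0 calls over all genes, and the list had an adjusted p of 0.55 with an estimated correlation.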
